A study of Anas platyrhynchos with 12 samples.

How the data were processed

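Breast muscle of ducks (Anas platyrhynchos) from an F2 population was profiled by RNA sequencing at 42 days of age. The labels place 6 samples in a group with a high breast muscle ratio (HB) and 6 in a group with a low breast muscle ratio (LB). Per the labels' protocols, the muscle was frozen after removal, RNA was extracted with Trizol and libraries were made with a TruSeq kit. The submitters' processing notes list fastp 0.18.0, HISAT2, StringTie 1.3.1 and DESeq2, without versions for HISAT2 and DESeq2. The genome build, the annotation release and the counting step are not given in the sources used here.

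The deposited table holds raw whole-number read counts for 16433 gene models in 12 libraries. Per the file headers, the authors added a mean FPKM per group, a log2 fold change between these means, a p-value and its adjusted value for each gene. FPKM values per library were computed here, to 2 decimals, from the counts, the library totals and the gene length that the authors' deposited mean FPKM implies. Lengths from the LB mean and from the HB mean differed by at most 0.465% over 10188 genes with a mean of at least 1 FPKM in both, and 1 gene with counts had no length and was set to 0 FPKM. The table holds 12 further columns with values per library, which were not used. The deposited log2 value equals the log2 ratio of the group mean FPKM, and a group mean of 0 was written as 0.001. The deposited p-values equalled those of DESeq2 1.42.0 with default settings within 1% for 100% of the 14981 genes compared. The column names give each library's group and a number (HB-1 to HB-6, LB-1 to LB-6), but they do not tie a library to a particular sample, so the number only names a library. The labels give no sex, batch, pairing or litter, and nothing states that the 12 samples came from separate birds, so p-values measure the spread between these samples.

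Total counts lay between 24090771 and 42503751 per library. Correlations of log2 expression between libraries lay between 0.951 and 0.989, and 0 pairs of libraries held identical values. The smallest chi-square per degree of freedom between libraries of a group was 69.4, so every pair differed by more than sampling noise. Of the gene models, 15747 carried an NCBI gene number and 686 were assembled models. A reference gene table (assembly GCF_047663525.1) matched 14057 of the numbers and was used only for symbols and for placing genes on Z, W or another chromosome. It may not be the assembly that was used for alignment, so no coordinates are printed. Several symbols are shared by more than 1 gene model. Their sequences were not compared, but reads of similar models may be split between them, which makes MYH1B, MKI67, CD163, LTBP4 and ZC3H11A uncertain.

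The design fixed before the data were examined assumed FPKM values and set edgeR as the test if counts were present. Counts were present, so genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 on the same model, two-sided, with a preset correlation between genes of 0.01. Of these lists, 31 had at least 5 tested members, and a list of W chromosome genes had 0. Each list was also tested with a correlation estimated from the data and with fry. Terms of the deposited GO and KEGG annotation with 10 to 500 tested genes were tested in the same way as the lists. Measures with 1 value per library were compared by an exact two-sided permutation test over 924 assignments, whose smallest p is 0.00216.

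The genes to name were set by a rule. Among genes with a symbol and a mean of at least 1 FPKM, the 12 largest differences per direction past the threshold were to be named, filled up by the smallest unadjusted p where fewer passed. Up to 4 members per list by smallest p were added, with MSTN, FST, IGF1, IGF2, MYOD1, MYOG, MYF5, PAX7, FBXO32 and TRIM63 always given where measured. TRIM63 had 0 counts in all 12 libraries and was not tested. Of the genes that the rule picked, 3 are not reported here and were not replaced.

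The procedure was tested on simulated counts for the HB and LB comparison with 12577 genes, of which 200 were changed, in 3 rounds. It recovered 7.5% of genes changed 1.5-fold, 52.5% of those changed 2-fold and 88.5% of those changed 4-fold, and false calls were 10.0%, 4.5% and 3.6% of all calls. The simulated genes varied independently of each other, so the simulation says nothing of lists whose members vary together. Alternatives covered DESeq2, limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.01, other scalings and filters, array weights, a rank test, a Z chromosome covariate, and the removal of each library in turn. Further alternatives, chosen after the data had been seen, left out HB-3 and HB-4 together, combined the removal of HB-4 with DESeq2 or with an estimated correlation, and left out symbols shared by several gene models.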

Results

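The series compared breast muscle of F2 ducks that differ in the share of breast muscle, to find genes related to this growth trait. RNA of 6 HB and 6 LB samples taken at 42 days of age was sequenced. LB libraries held 24090771 to 39718065 counts and HB libraries 33124019 to 42503751. In each library between 13406 and 13942 gene models had a count, and the 10 most counted genes took 19.8% to 29.7% of the reads. Each SE of a log2 difference is its absolute value divided by the square root of the edgeR F value. It and the intervals rest on the spread between the 6 libraries of a group, moderated by that of other genes.

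In edgeR, single genes did not separate the HB and LB groups more often than chance gives. The smallest p belonged to CYSTM1, a small cysteine-rich membrane protein, with 46.0 ± 9.89 FPKM in HB and 30.4 ± 4.07 FPKM in LB (SD, n = 6) and a log2 difference of 0.65 ± 0.14 (SE). All 6 HB libraries lay above the highest LB library for CYSTM1, but its adjusted p in edgeR was 0.977. EDN2, which encodes the vasoconstrictor peptide endothelin 2, had 5.77 ± 2.98 FPKM in HB and 2.49 ± 0.53 FPKM in LB. FREM2, a basement membrane protein, had 3.82 ± 1.22 FPKM in HB and 7.16 ± 0.95 FPKM in LB, with a log2 difference of -0.86 ± 0.21. MTSS1, a scaffold protein of the actin cytoskeleton, had 28.5 ± 5.66 FPKM in HB and 39.7 ± 3.60 FPKM in LB. Library HB-4 was lowest for FREM2 and MTSS1, with 1.51 and 18.3 FPKM. Without HB-4 their log2 differences in edgeR went from -0.86 to -0.70 and from -0.44 to -0.34.

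No gene passed the threshold: of 12577 genes tested with edgeR, 0 had an adjusted p under 0.05 and the smallest adjusted p was 0.977. Unadjusted p-values under 0.05 were found for 579 genes, 294 with higher and 285 with lower values in HB, where chance gives about 629. Groups did not overlap for 20 genes, where chance gives 27 (0.216%). DESeq2 called 1 gene, which is also the call of the authors' deposited table. The common biological coefficient of variation between libraries was 33.1%.

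The other genes with the smallest p and higher values in HB were PHF13, PANK4, SLC19A2, RSAD1, GTPBP10, SMARCD3, MAP7D1, HMCN2 and CUTC, with log2 differences from 0.38 to 0.88. SLC19A2 encodes a thiamine transporter, and it had 5.08 ± 1.26 FPKM in HB and 3.18 ± 0.81 FPKM in LB. SMARCD3, a muscle subunit of the SWI/SNF chromatin remodelling complex, had a log2 difference of 0.42 ± 0.12. PANK4, a member of the pantothenate kinase family, had 14.5 ± 1.23 FPKM in HB and 11.5 ± 1.64 FPKM in LB. With lower values in HB followed ADCY2, DCLRE1A, ZMYM4, CPZ, UGT8, GLB1L, ARHGEF12, SEMA7A, TENM3 and an assembled model named ZC3H11A, with log2 differences from -1.55 to -0.28. CPZ, a carboxypeptidase of the extracellular matrix, had 2.08 ± 1.09 FPKM in HB and 5.55 ± 2.83 FPKM in LB. UGT8, an enzyme of galactosylceramide synthesis in myelin, had 1.00 ± 0.29 FPKM in HB and 2.14 ± 0.99 FPKM in LB. SEMA7A, a membrane-anchored semaphorin, had 34.6 ± 6.61 FPKM in HB and 50.1 ± 9.13 FPKM in LB. ADCY2, an adenylate cyclase, had 6.95 ± 0.87 FPKM in HB and 9.82 ± 1.61 FPKM in LB. For each of these genes but SLC19A2, GTPBP10 and SMARCD3, all 6 HB libraries lay on the same side of the LB mean FPKM. SLC19A2 held 3.13 FPKM in HB-2, under its LB mean of 3.18 FPKM. GTPBP10 and SMARCD3 held 9.32 and 4.75 FPKM in HB-1, under LB means of 9.53 and 4.79 FPKM. The genes were picked by the smallest p, so libraries on the same side are not separate evidence of a difference.

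**Figure D1:**
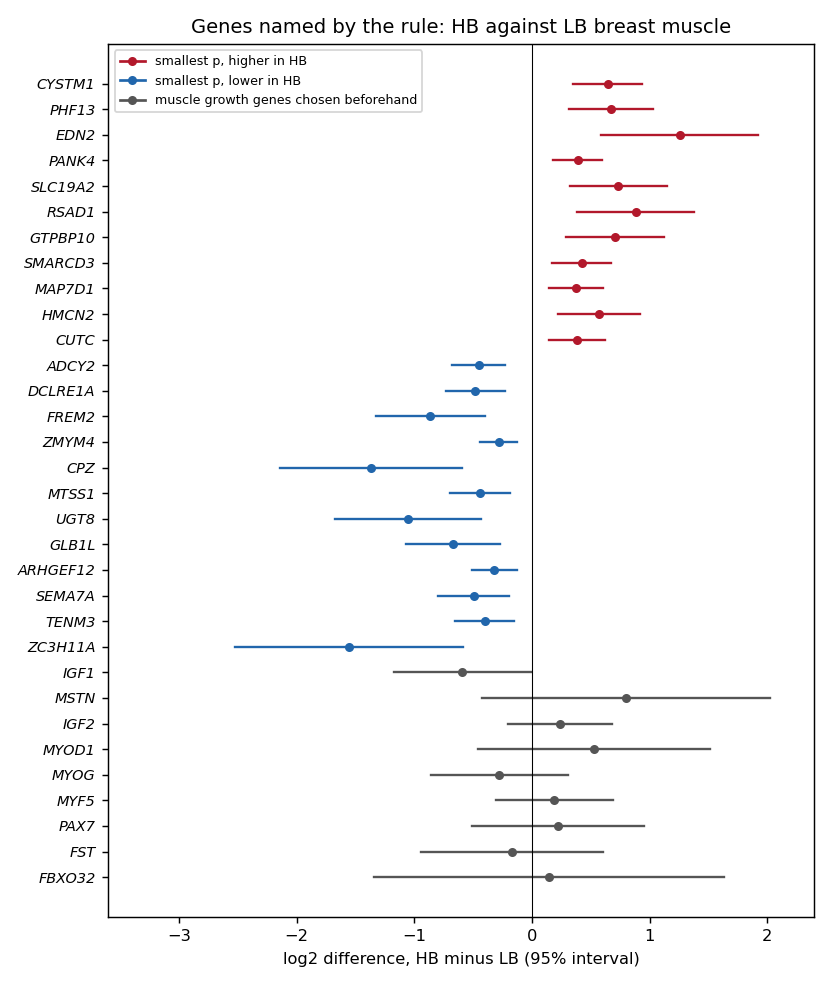
The points are log2 differences between HB and LB from edgeR and the lines their 95% intervals, with 6 libraries per group. The first 23 genes were picked by the smallest p in either direction and the last 9 were fixed beforehand; the adjusted p was 0.977 for CYSTM1, the gene with the smallest p.

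The genes that set muscle mass in birds and mammals had overlapping values. IGF1, a growth factor of muscle, had 1.40 ± 0.44 FPKM in HB and 2.20 ± 0.97 FPKM in LB, a log2 difference of -0.59 ± 0.27 that did not pass the threshold. MSTN, which encodes myostatin, an inhibitor of muscle growth, had 36.8 ± 44.7 FPKM in HB and 21.9 ± 8.14 FPKM in LB. The HB mean of MSTN rests on library HB-4, which held 126.9 FPKM where the other 11 libraries held 11.7 to 32.7, and without HB-4 the log2 difference turned from 0.80 to -0.20. MYOD1, a myogenic transcription factor, had 714 FPKM in HB-4 and 96.2 to 276 FPKM elsewhere, and its log2 difference turned from 0.52 to -0.18 without HB-4. FBXO32, a ubiquitin ligase of muscle atrophy, had 158.6 FPKM in HB-4, and its log2 difference turned from 0.14 to -0.71 without that library. The log2 differences of IGF2, MYF5 and PAX7 were 0.24 ± 0.20, 0.19 ± 0.23 and 0.22 ± 0.34, and leaving out single libraries moved them from 0.14 to 0.38, from 0.04 to 0.30 and from 0.04 to 0.45. Those of MYOG and of FST, which encodes the myostatin antagonist follistatin, were -0.28 ± 0.27 and -0.17 ± 0.36, and without HB-4 they were -0.09 and -0.51. At the other end of the single-library range, MYOG had -0.405 without HB-2 and FST had -0.01 without LB-6.

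**Figure D2:**
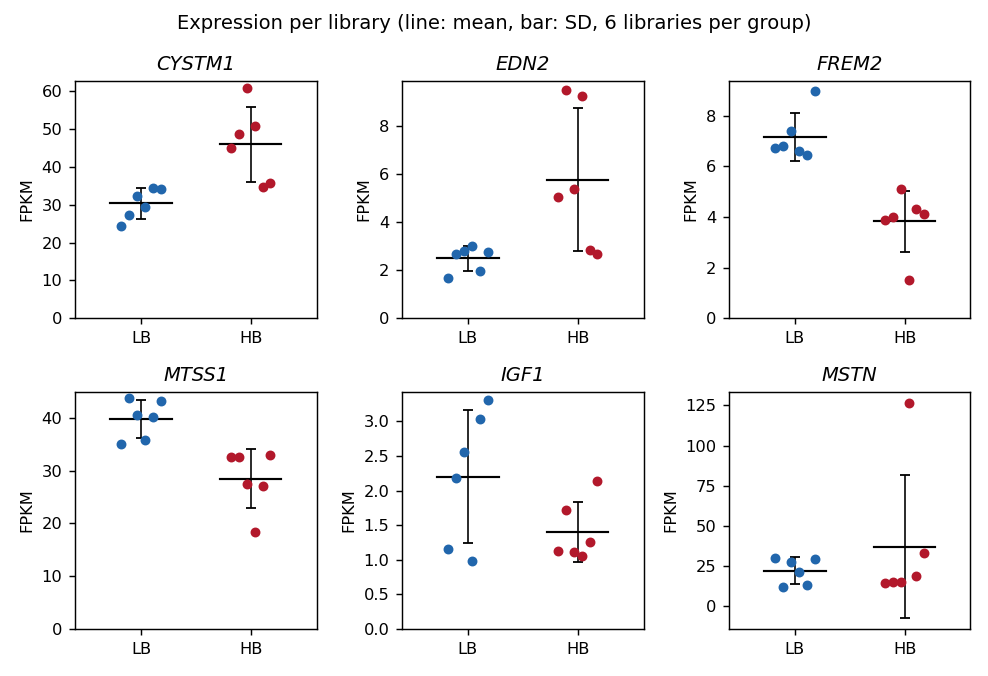
Each point is the FPKM of 1 library, with the group mean as a line and the SD as a bar, for 6 LB and 6 HB libraries. CYSTM1, FREM2 and MTSS1 show groups without overlap, while the HB mean of MSTN of 36.8 FPKM is set by 1 library with 126.9 FPKM.

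Antiviral and interferon response genes were lower in HB and had the smallest p of all lists in camera with the preset correlation, but library LB-5 carried much of the difference. All 29 tested members had negative log2 differences, with a median of -0.47, and camera gave the list an adjusted p of 1.4e-09 with the preset correlation. With an estimated correlation of 0.626 between its genes the list gave an adjusted p = 0.879. IFIT5 had 2.67 ± 2.26 FPKM in HB and 16.9 ± 30.3 FPKM in LB, and RSAD2, the antiviral enzyme viperin, had a log2 difference of -2.38 ± 0.85 (SE). Library LB-5 had a list mean 1.80 log2 units above the mean of all libraries, with 78.0 FPKM of IFIT5 and 34.5 FPKM of RSAD2. The mean of the list per library was -0.25 ± 0.32 in HB and 0.25 ± 0.87 in LB (SD, n = 6, exact permutation p 0.234). USP18 and CMPK2 had log2 differences of -1.86 ± 0.71 and -1.91 ± 0.75. Without LB-5 the log2 differences of IFIT5, RSAD2, USP18 and CMPK2 shrank to -0.77, -0.88, -0.72 and -0.50, and the adjusted p of the list was 0.00393 with the preset correlation.

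The lists of oxidative phosphorylation, glycolysis and the tricarboxylic acid cycle were higher in HB by small amounts, while those of fatty acid oxidation and of mitochondrial genome genes were not called (adjusted p 0.0859 and 0.872 in camera). Of 61 nuclear genes of oxidative phosphorylation, 55 had positive log2 differences, with a median of 0.14 (adjusted p 3.64e-05 in camera, adjusted p = 0.897 with an estimated correlation). The mean of this list per library was highest in HB-1 (0.34) and HB-2 (0.31) and lay at 0.09 in HB-3. It lay at -0.03, -0.23 and -0.17 in HB-4, HB-5 and HB-6, and between -0.36 and 0.17 in LB. COX6B1, a subunit of cytochrome c oxidase, had 70.5 ± 16.1 FPKM in HB and 48.2 ± 12.4 FPKM in LB. A model of cytochrome c, CYCS, went the other way with 44.3 ± 11.6 FPKM in HB and 105.7 ± 77.5 FPKM in LB. The LB mean of CYCS rests on LB-2, LB-3 and LB-4, with 198, 190 and 131 FPKM. The other LB libraries held 34.8 to 41.1 FPKM, within the HB range of 29.8 to 59.2 FPKM. Of 32 glycolysis and glycogen genes, 27 had positive log2 differences, with a median of 0.13 (adjusted p 0.00387 in camera, adjusted p = 0.879 with an estimated correlation). PGM1, which links glycogen to glycolysis, had 752 ± 94.6 FPKM in HB and 650 ± 43.2 FPKM in LB. UGP2 and the glycogen branching enzyme GBE1 had log2 differences of 0.42 ± 0.17 and 0.84 ± 0.32, and GBE1 held 19.5 FPKM in HB-4 and 4.36 to 6.96 FPKM in the other HB libraries. Without HB-4 these log2 differences were 0.28 for UGP2 and 0.34 for GBE1. Of 24 genes of the tricarboxylic acid cycle, 20 had positive log2 differences, with a median of 0.09 (adjusted p 0.0259 in camera, adjusted p = 0.897 with an estimated correlation), and PDP1, a phosphatase that activates pyruvate dehydrogenase, had 34.7 ± 9.50 FPKM in HB and 24.7 ± 6.04 FPKM in LB. Without LB-6 the calls of oxidative phosphorylation, glycolysis and the tricarboxylic acid cycle ended, with adjusted p of 0.0862, 0.0532 and 0.338 in camera. The call of glycolysis also ended without LB-2 (adjusted p 0.0502 in camera), and that of the tricarboxylic acid cycle without LB-2, HB-1 or HB-2 (adjusted p 0.0722, 0.303 and 0.135).

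Proteasome genes were higher in HB in 28 of 29 tested members, with a median log2 difference of 0.11 (adjusted p 7.75e-05 in camera, adjusted p = 0.869 with an estimated correlation). The core subunit PSMB1 had 100.7 ± 10.6 FPKM in HB and 87.9 ± 5.41 FPKM in LB, and the ATPase PSMC3 had 64.7 ± 4.94 FPKM in HB and 58.2 ± 3.55 FPKM in LB. The mean of the list per library was 0.05 ± 0.07 in HB and -0.05 ± 0.05 in LB (SD, n = 6, exact permutation p 0.0238, adjusted p 0.503 over the 31 lists). It was highest in HB-4 (0.15) and HB-3 (0.12) and lay between -0.04 and 0.03 in the other HB libraries, and without both of them the list had an adjusted p of 0.0119 in camera.

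Nerve and Schwann cell genes were lower in HB in 13 of 16 tested members, with a median log2 difference of -0.35 (adjusted p 0.000427 in camera). With an estimated correlation the unadjusted p was 0.0169 and the adjusted p = 0.524. MBP, which encodes myelin basic protein, had 8.45 ± 2.15 FPKM in HB and 14.6 ± 6.90 FPKM in LB. DRP2, a protein of the Schwann cell membrane, had a log2 difference of -0.83 ± 0.26. The mean of the list per library was -0.16 ± 0.14 in HB and 0.16 ± 0.26 in LB (SD, n = 6, exact permutation p 0.0325, adjusted p 0.503 over the 31 lists).

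Cell cycle genes were lower in HB in 37 of 44 tested members, with a median log2 difference of -0.22 (adjusted p 7.75e-05 in camera, adjusted p = 0.897 with an estimated correlation). The mitotic genes BUB1 and CDC20 had 1.51 ± 0.42 and 6.56 ± 2.77 FPKM in HB and 2.45 ± 0.91 and 9.88 ± 2.68 FPKM in LB. Without HB-4 the median was -0.12 (adjusted p 0.021 in camera). The list mean was highest in LB-6, at 1.04, and lowest in HB-5, at -1.06, and the call ended without LB-6 (adjusted p 0.338 in camera) and without HB-5 (adjusted p 0.165).

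Fast fibre contractile genes were higher in HB in 14 of 17 tested members and endothelial genes lower in 20 of 27, with adjusted p of 0.0225 and 0.0167 in camera and adjusted p = 0.897 for both with an estimated correlation. Both calls ended without HB-4, with adjusted p of 0.326 and 0.291 in camera. The fast fibre call also ended without LB-2, LB-5, LB-6 or HB-6 (adjusted p 0.0873, 0.0563, 0.158 and 0.0601), and when symbols shared by several gene models were left out (adjusted p 0.086). The endothelial call also ended without LB-2 or LB-5 (adjusted p 0.155 and 0.0561). In HB-4 the fast fibre list lay 1.91 log2 units above the mean of all libraries, where the myosin heavy chain model MYH1B with the smallest p held 52.0 FPKM and its log2 difference went from 5.40 ± 1.89 (SE) to 2.11 without HB-4. JSRP1, a protein of the sarcoplasmic reticulum junction, had 184 ± 46.1 FPKM in HB and 134.7 ± 26.4 FPKM in LB. The endothelial genes PECAM1 and CLDN5 had log2 differences of -0.22 ± 0.11 and -0.53 ± 0.27, and ESM1 went the other way with 1.31 ± 0.57.

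**Figure D3:**
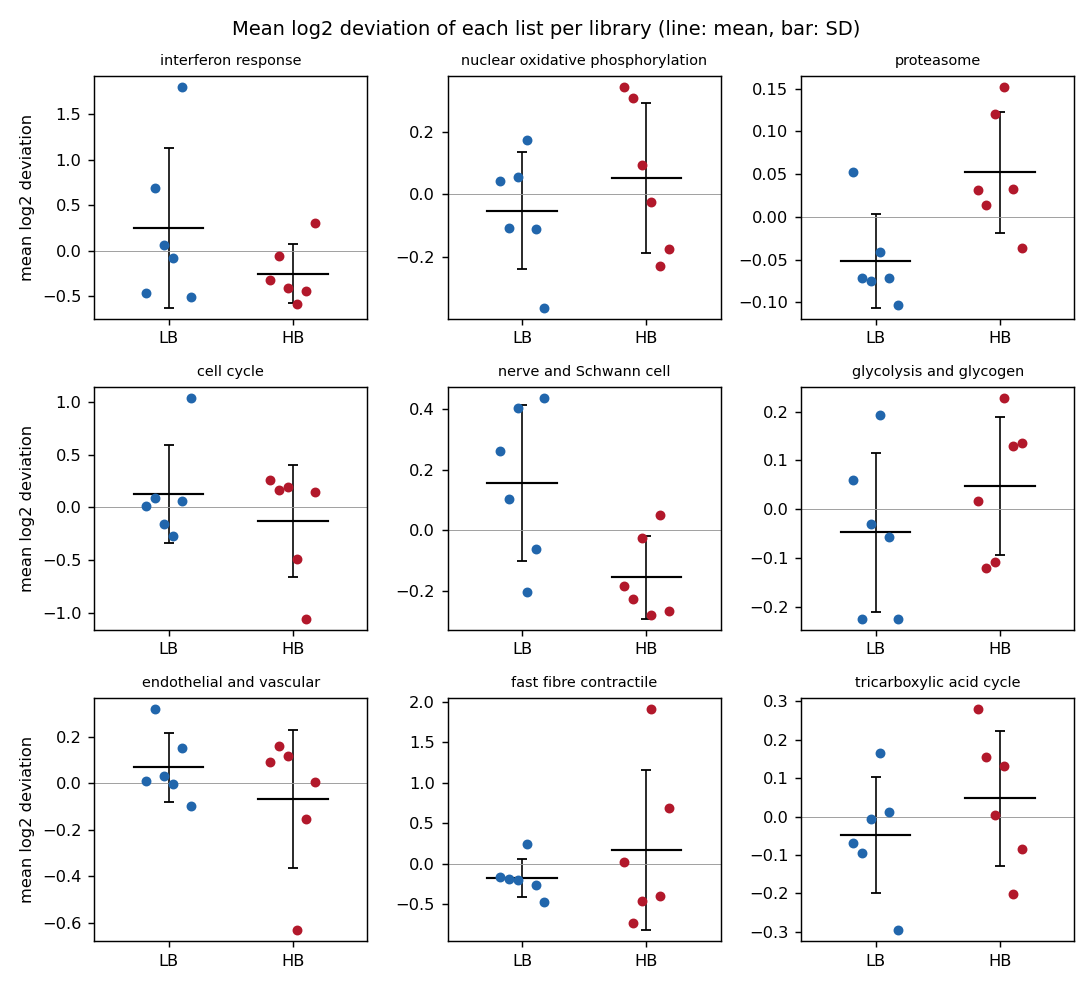
Each point is the mean log2 deviation of a list in 1 library from its mean over the 12 libraries, with the group mean as a line and the SD as a bar, for the 9 lists with an adjusted p under 0.05 in camera with the preset correlation. LB-5 lies 1.80 above the mean for interferon response genes and HB-4 1.91 above it for fast fibre genes.

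In total 9 of 31 lists were called with the preset correlation, 0 with an estimated correlation and 0 with fry. The list means per library gave exact permutation p (n = 6 per group) of 0.416 for oxidative phosphorylation, 0.303 for glycolysis, 0.346 for the tricarboxylic acid cycle, 0.413 for cell cycle, 0.405 for endothelial and 0.506 for fast fibre genes. Across all lists 0 members passed when adjusted over all genes, and 0 when adjusted over the list alone. The other 22 lists were not called, among them myogenic regulators (adjusted p 0.605 in camera), growth factor and TOR signalling (0.539), myostatin, activin and BMP signalling (0.791), muscle atrophy and autophagy (0.0507), slow fibre (0.872), sarcomere scaffold (0.0728) and immediate early genes (0.0535). In camera the adjusted p of the atrophy list ranged from 0.0152 without HB-3 to 0.606 without HB-4. That of the sarcomere scaffold list ranged from 6.31e-05 without LB-1, where it was called higher in HB, to 0.945 without HB-4. The remaining cell type lists were adipocyte (0.134), macrophage (0.186), cartilage and tendon (0.307), lymphocyte (0.488), skin (0.506), erythrocyte (0.539), extracellular matrix and fibroblast (0.872) and smooth muscle genes (0.954). The further lists were the Z chromosome panel (0.0728), fatty acid oxidation (0.0859), ribosomal protein (0.176), heat shock (0.354), circadian clock (0.514), focal adhesion (0.769) and mitochondrial genome genes (0.872). MUSK, the receptor kinase of the neuromuscular junction, was the myogenic list member with the smallest p, with 1.48 ± 0.22 FPKM in HB and 2.01 ± 0.23 FPKM in LB. Median, mean and test differed in sign for the myogenic, slow fibre, erythrocyte, smooth muscle, mitochondrial genome and myostatin lists. The immediate early list lay 2.89 log2 units above the mean of all libraries in HB-4, and without HB-4 it was called lower in HB (adjusted p 0.000476 in camera, adjusted p = 0.711 with an estimated correlation). With HB-4 kept, camera called it higher in HB without LB-1 (adjusted p 0.0085), without LB-4 (0.0298) and with the Z chromosome covariate (0.000393). The calls of the immediate early list thus went both ways. Without HB-4 the extracellular matrix, myostatin signalling and Z chromosome panel lists were also called lower in HB, with adjusted p of 0.0187, 0.0247 and 0.0165 in camera and adjusted p = 0.903, 0.711 and 0.903 with an estimated correlation. The call of the Z chromosome panel rests on HB-3, since its adjusted p was 0.845 without HB-3 and 0.676 without HB-3 and HB-4.

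Among 1102 annotated terms, fatty acid catabolic process was the 1 term called, higher in HB with a median log2 difference of 0.19 over 18 genes (adjusted p 0.014 in camera, adjusted p = 0.999 with an estimated correlation). FABP3, a fatty acid carrier of muscle in the fatty acid oxidation list, had 390 ± 443 FPKM in HB and 107 ± 14.6 FPKM in LB, with 1184 FPKM in HB-4 and 647 FPKM in HB-1, and without HB-4 its log2 difference went from 1.92 to 1.15. Leaving out single libraries gave from 0 to 10 called terms, with 0 without LB-6, HB-1 or HB-2 and 10 without HB-5.

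The balance of slow and fast fibre genes did not separate the groups. The slow to fast index was -2.61 ± 0.98 in HB and -2.13 ± 0.78 in LB (log2, SD, n = 6, exact two-sided permutation p 0.372). HB-4 lay at -4.31, and without it the difference between the groups went from -0.48 to -0.14. MB, which encodes the oxygen carrier myoglobin, had 1295 ± 901 FPKM in HB and 459 ± 256 FPKM in LB, and did not pass the threshold. The 10 most counted genes took 24.6 ± 3.31% of reads in HB and 24.6 ± 1.17% in LB (SD, n = 6, exact permutation p 0.965). The Z chromosome panel lay at 0.86 ± 0.13 in HB and 0.92 ± 0.02 in LB relative to the median of all genes (log2, SD, n = 6, exact permutation p 0.277). Library HB-3 had 0.61 and the other 11 libraries 0.84 to 0.97. NIPBL, a cohesin loading factor with a model placed on W, had 2.56 FPKM in HB-3 and 0.18 to 0.28 FPKM in the others.

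**Figure D4:**
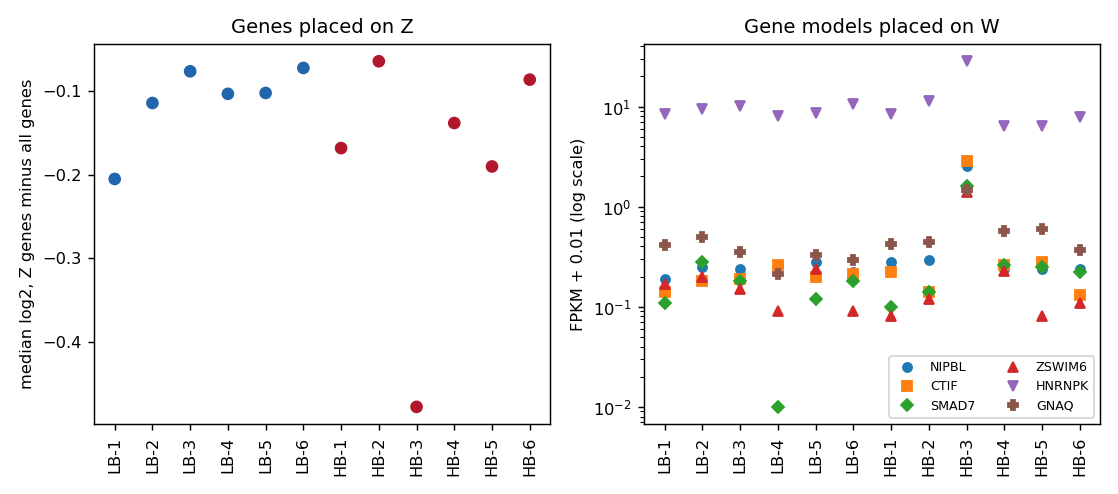
Each point is 1 of the 12 libraries, with the median of the 557 tested genes placed on Z relative to that of all genes (log2) and the FPKM + 0.01 of the 6 gene models placed on W that stand out in HB-3. HB-3 lies at -0.48 for the Z genes and has 2.56 FPKM of NIPBL.

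Genes that mark position along the body, and the contractile gene TNNC1, set HB-4 apart from the other libraries. HOXC10, a gene of the hindlimb and posterior trunk, held 27.1 FPKM in HB-4 and 0 FPKM in the other 11 libraries, and PITX1, a hindlimb gene, held 3.54 FPKM there and at most 0.74 FPKM elsewhere. TNNC1, the troponin C of slow and cardiac muscle, held 5.56 FPKM in HB-4 and 1186 to 2468 FPKM elsewhere, and TBX5, a forelimb gene, held 0 FPKM in HB-4 and 0.19 to 0.96 FPKM elsewhere. The first principal component took 24.7% of the variance and set HB-4 at -93.8, with the other libraries from -7.7 to 21.8.

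**Figure D5:**
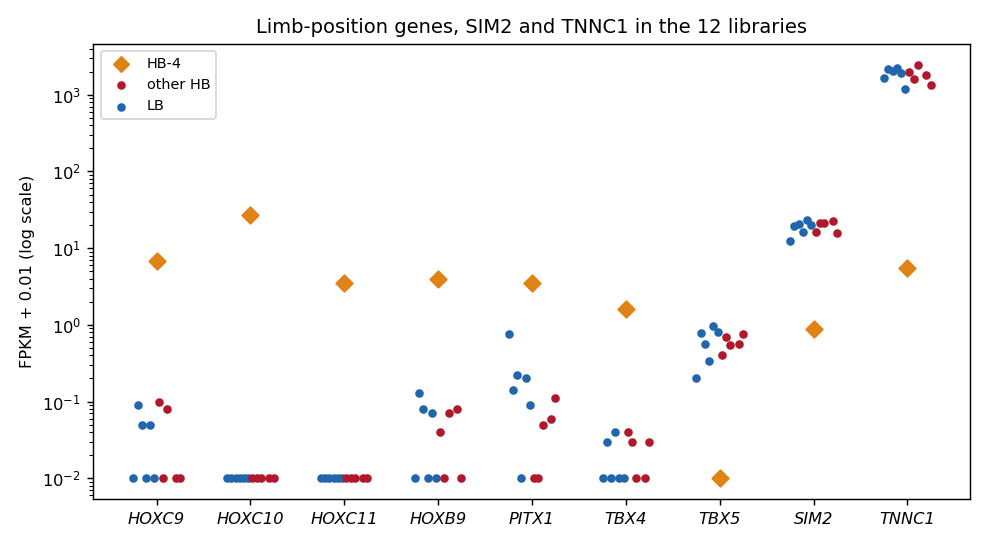
Each point is the FPKM + 0.01 of 1 library for genes that mark limb position and for SIM2 and TNNC1, with HB-4 as a diamond among 6 HB and 6 LB libraries. HOXC10 has 27.1 FPKM and TNNC1 5.56 FPKM in HB-4.

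The authors' deposited table gives 1 gene with an adjusted p under 0.05, a model annotated as HEAT repeat-containing protein 7A (adjusted p 4.42e-10), and 729 genes with a p under 0.05. Its counts were 239 in LB-2, 56 in LB-5 and 0 in the other 10 libraries, and 0 genes were called in both tests. The gene was below the filter of the edgeR test, but edgeR without that filter also called 0 of 15209 genes (800 at an unadjusted p under 0.05, smallest adjusted p 0.888). Among the 12577 genes in both tests, log2 signs were alike for 90.6%, and for 100% of those with an unadjusted p under 0.05 in edgeR.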

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

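The tests of hindlimb position and of mixed tissue in HB-4, of a female bird in HB-3, of leukocytes in LB-5 and of other splits for genes were chosen only after the result was seen. A library was singled out where its gap to the nearest library of its group, as a share of the group's range, exceeded Dixon's limit, which chance gives in about 1 in 20 groups. Of 372 groups of values examined, 40 were beyond this limit where chance gives about 19, and 25 of the 40 belonged to HB-4. Most of these groups are genes picked by the smallest p from the same 12 libraries, so 19 is no firm baseline. Over all 12577 tested genes, HB-4 was beyond the limit for 5.93%, and each other library for 0.49% to 2.49%. Unless another reference is named, values below are log2 deviations from the mean of the other 5 libraries of the group.

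HB-4 lay above its group for these genes: NR4A2 by 5.26, MYC by 3.51, NR4A1 by 2.49, BHLHE40 by 2.83, CCN2 by 4.01, ANKRD1 by 3.33, DNAJB6 by 1.02, ITGA11 by 1.48 and BMP4 by 1.54. It also lay above for MSTN by 2.89, a MYH1B model by 4.66, GBE1 by 1.84, MYOCD by 2.78 and KRT14 by 2.32. It lay below for FREM2 (-1.44), MTSS1 (-0.67), MYOG (-1.71), EYA1 (-1.76) and RPL3 (-0.61). Its list means were apart for immediate early genes (3.47), sarcomere scaffold genes (1.14), heat shock genes (1.07), myostatin signalling genes (0.73), atrophy genes (0.50) and focal adhesion genes (0.26).

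The HB-4 profile also differed in genes that mark position along the body and in a contractile gene. HOXC10, a gene of the hindlimb and posterior trunk, held 27.1 FPKM in HB-4 and 0 FPKM in the other 11 libraries, and TNNC1, a troponin C, held 5.56 FPKM there against a median of 1921 FPKM. All 6 hindlimb and posterior markers examined were highest in HB-4 and TBX5, a forelimb gene, was lowest, so tissue from a hindlimb or posterior position is a candidate explanation; these markers were listed after the library had been noticed. A mixture with another tissue that kept a breast muscle share of 10% or more is argued against by 7 abundant genes below 10% of their median. The highest such count in any other library was 4, in HB-3. Shares under 10% were not tested, and how small a share these genes leave open differs by gene. TNNC1 lay at 0.289% of its median in HB-4, which by that gene leaves only a far smaller share. G0S2 held 88.7 FPKM against a median of 978 FPKM, close to the bound. Handling or RNA quality was not excluded by the bound set beforehand, but that bound could not decide the question. HB-4 had 13 genes with at least 1 FPKM there and at most 0.1 FPKM in each other library. HB-3 had 49 such genes and the other 10 libraries at most 2. Of the 49 genes of HB-3, 17 were placed on W and 32 were not placed. They may therefore come from the sex of that bird, and so set no scale for handling. Some of these 13 genes, HOXC10 among them, had been seen when that bound was set. No biological explanation from the design was tested, and a mislabelled sample was not tested apart from tissue position.

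HB-3 lay below its group for the Z chromosome panel (-0.31 as a list mean, -0.30 relative to all genes) and for SMAD2 (-0.47), a gene of that panel. The 557 tested genes placed on Z had a median deviation of -0.34 in HB-3 from the other 11 libraries, while 6 of the 14 tested gene models placed on W, among them those of NIPBL and CTIF, were more than 1 log2 unit above every other library and the other 8 were not. A shift of the whole library is argued against, since the lowest median of any other chromosome with at least 100 tested genes, on the same scale, was -0.057. A single Z copy and a W chromosome, as in a female bird, may account for these values, as a hypothesis from the same data; of the 49 genes with at most 0.1 FPKM outside HB-3, 17 were placed on W, 32 were not placed and 0 lay on other chromosomes.

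The interferon list mean of LB-5 did not exceed Dixon's limit in LB and is weighed here because the list was called. LB-5 had the highest value of 23 of the 29 tested interferon genes, which argues against stray reads of a few genes. More leukocytes in that piece of muscle could not be told apart from a response of the muscle itself. Relative to the mean of all 12 libraries, the lymphocyte list lay at -0.104 in LB-5, within the spread of LB (0.04 ± 0.40, SD, n = 6). The forecast took a value below the LB mean as a sign against leukocytes, but the gap was within that spread. The macrophage and antigen presentation list lay at 0.333 in LB-5, the highest of the 6 LB libraries. It shares TAP1 with the interferon list, but TAP1 is only 1 of its 27 tested members. TAP1 was highest in LB-2, with 25.2 FPKM there and 19.3 FPKM in LB-5. MYF5 lay below the group in LB-5 (-0.79).

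Single values in other libraries are given without explanation. LB-6 lay apart for cell cycle genes (1.09), SQSTM1 (-0.92) and the Z chromosome panel relative to all genes (0.06). LB-1 lay apart for sarcomere scaffold genes (1.15), GRB10 (1.34) and RPL38 (0.43), and LB-4 for BHLHE40 (1.25). HB-6 lay apart for CD4 (2.05), SEMA7A (0.51) and NDUFA2 (-0.58), and HB-1 for KRT75 (0.83).

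Chance cannot be excluded for the lists and terms called between the groups. For genes the splits decide nothing, since the real count is 0 and all 100 of the splits drawn from 462, the real one included, must reach it (highest other split 1). For lists, 72 of 100 splits gave at least the 9 calls of the real split, with a median of 11 in the other splits and 20 in the highest. For annotated terms, 85 of 100 gave at least the 1 call, with a median of 5 in the other splits and 30 in the highest. The real counts thus lay below what another split typically gave. With an estimated correlation, 0 lists and 0 terms were called for the real split. The count of 30 terms, several times the real one, may come from a structure of the samples or from genes that vary together, which was not tested for that split.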

How the results depend on the processing

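The tests without HB-3 and HB-4 together, those that combined the removal of HB-4 with DESeq2 or with an estimated correlation, those without symbols of several gene models and most tests of annotated terms were chosen only after the result was seen. No paired analysis was possible because the library numbers do not pair HB with LB birds. The count of genes past the threshold was 0 in 28 of 30 settings. DESeq2 gave 1 gene, 1 of them lower in HB, and DESeq2 without HB-4 gave 4 genes, 4 of them lower. The DESeq2 gene has counts in 2 libraries only and is removed by the filter of the main test, but edgeR without that filter also gave 0 genes (smallest adjusted p 0.888), so the filter does not account for the missing call. DESeq2 shared 1 gene with the calls of the authors' deposited table.

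Of 152 named genes, 15 had the other sign in at least 1 setting, without a call in either. FBXO32 turned in limma on log2 FPKM, with -0.328 for a pseudocount of 1, -0.346 for 0.1, -0.348 for 0.01, -0.282 after median-of-ratios scaling, -0.329 after quantile scaling, -0.326 on TPM, -0.328 without the trend and -0.955 with array weights. Array weights also turned MSTN (-0.034), MYOD1 (-0.122), SCD (-0.109), NR4A2 (-0.071) and MYBPC1 (-0.262), and the Z chromosome covariate turned FST (0.056).

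DESeq2 without HB-4 gave MSTN -0.202, MYOD1 -0.184, FBXO32 -0.709, SCD -0.011, BHLHE40 -0.036, NR4A2 -0.609, MYC -0.047, UNC45B -0.008, KRT14 -0.249 and MYBPC1 -1.103, and a second MYH1B model with 2.218 in the main test, not the one printed with 5.40 in the report, -0.094. Without HB-3 and HB-4, edgeR gave MSTN -0.119, MYOD1 -0.18, FBXO32 -0.71, NR4A2 -0.522, MYC -0.05, KRT14 -0.255 and MYBPC1 -0.91.

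Leaving out each library in turn moved log2 differences over these ranges: MSTN -0.201 to 0.969, MYOD1 -0.183 to 0.75, FBXO32 -0.706 to 0.435, SCD -0.013 to 1.241, BHLHE40 -0.033 to 1.241, the second MYH1B model -0.092 to 2.448, NR4A2 -0.606 to 2.518 and MYC -0.045 to 1.584. The further ranges were UNC45B -0.007 to 0.555, ACTC1 -1.79 to 0.633, KRT14 -0.248 to 0.94, KRT75 -0.482 to 0.1, MYBPC1 -1.101 to 3.263 and ANKRD1 -2.406 to 0.128. The group difference of the share of the 10 most counted genes ranged from -0.954 to 1.027 percentage points.

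The number of lists called was 0 with an estimated correlation, 0 with fry, 15 with the Z chromosome covariate and 6 to 15 without single libraries. Without HB-4 and with an estimated correlation it was 0. For annotated terms the count was 0 with an estimated correlation, 5 with the Z chromosome covariate, 8 without HB-3 and HB-4, and 0 to 10 without single libraries. The cause of these changes was not tested.

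Of 619 list values compared, 68 in 15 lists had the other sign, 3 of them with a call, and those lists are given here by adjusted p. Fry gave smooth muscle genes 0.992. With log2(FPKM + 0.1), extracellular matrix, mitochondrial genome and smooth muscle genes had 0.979 and slow fibre genes 0.872. With the Z chromosome covariate, the Z chromosome panel, erythrocyte and slow fibre genes had 0.91, mitochondrial genome genes 0.654 and myostatin signalling genes 0.741. Without symbols of several gene models, mitochondrial genome and myostatin signalling genes had 0.864.

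Without HB-3 and HB-4 camera gave adipocyte 0.889, cartilage 0.664, circadian 0.676, ribosomal 0.844, extracellular matrix 0.142, focal adhesion 0.971, heat shock 0.0763, immediate early 0.00188, lymphocyte 0.467 and smooth muscle genes 0.294. Without HB-4 and with an estimated correlation, adipocyte, cartilage, ribosomal, focal adhesion and lymphocyte genes had 0.914, circadian, extracellular matrix, heat shock and smooth muscle genes 0.903, and immediate early genes 0.711.

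Leaving out each library in turn gave these ranges of adjusted p in camera: adipocyte 0.0133 to 0.641, cartilage 0.0251 to 0.719, circadian 0.162 to 0.813, ribosomal 0.00858 to 0.727, erythrocyte 0.0739 to 0.972, extracellular matrix 0.0187 to 0.877, focal adhesion 0.435 to 0.878 and heat shock genes 0.028 to 0.901. The other ranges were immediate early 0.000476 to 0.307, lymphocyte 0.0145 to 0.707, mitochondrial genome 0.243 to 0.983, myostatin signalling 0.0247 to 0.987, slow fibre 0.243 to 0.983 and smooth muscle genes 0.256 to 0.973.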

Other observations

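All values in this part were looked at only after the libraries had been seen to differ, and the tests with DESeq2 without HB-4 were chosen after seeing the data. Myosin heavy chain models that share the symbol MYH1B, whose sequences were not compared, went both ways in HB-4. There 4 models held 67.1, 52.8, 52.0 and 32.4 FPKM. In LB-6 the same 4 models held 3.18, 2.13, 0.27 and 0 FPKM. The most abundant MYH1B model was lowest in HB-4, with 972 FPKM there and 1112 to 2830 FPKM in the other libraries, and 2 other MYH1B models were high in both HB-4 (793 and 257 FPKM) and LB-1 (439 and 220 FPKM), as was an MYH8 model (316 and 165 FPKM). EN2 (5.88 FPKM) and PVALB (1.09 FPKM), the calcium buffer parvalbumin of fast muscle, were found in HB-4 and at most at 0.1 FPKM elsewhere. Among abundant genes, G0S2, an inhibitor of fat breakdown, held 88.7 FPKM in HB-4 against a median of 978 FPKM and GATM, an enzyme of creatine synthesis, 3.12 against 102.8 FPKM.

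Without HB-4, FREM2 and MTSS1 were called lower in HB by DESeq2, with log2 differences of -0.70 and -0.34 and adjusted p of 7.91e-06 and 0.00361. The same DESeq2 test also called an assembled model without a symbol and the gene model with counts in LB-2 and LB-5 only. In edgeR without HB-4 the smallest adjusted p was 0.149, and FREM2, with this value, had a log2 difference of -0.70 ± 0.11 (SE). MTSS1 had an adjusted p of 0.995 in edgeR without HB-4. With HB-4 kept, FREM2 was lower than the LB mean in 6 of 6 HB libraries. It held 1.51 FPKM in HB-4, 3.86 to 5.12 FPKM in the other HB libraries and 6.45 to 8.99 FPKM in LB. FREM2 was picked by its small p, so libraries on the same side are not separate evidence of a difference.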
